A study of Arabidopsis thaliana with 9 samples.

How the data were processed

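Leaves of 3-week-old Arabidopsis thaliana plants grown at 22 °C with 16 h of light and 8 h of dark were the source of all libraries, per the labels. Nascent RNA was measured by nuclear run-on (NRO), in which transcripts already started in isolated nuclei are extended with biotin-UTP and then captured on streptavidin beads. Steady-state nuclear RNA (RNA) was measured beside it. The genotypes were Col-0, the wild-type accession, and the lines labelled nrpd1-3 and nrpe1-11, mutants of the largest subunits of Pol IV and Pol V. Each combination of assay and genotype had 1 library, which gives 6 groups of 1. Library construction used a stranded mRNA kit for both assays, per the labels' protocols, and the protocol text of the RNA samples repeats the bead capture of the NRO samples. A further 3 samples of chromatin precipitated with an antibody against the Pol II carboxy-terminal domain were not analysed here.

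The deposited values are whole-number read counts per gene, made by the authors with HTSeq, per the submitters' processing notes. Those notes also name Trimmomatic 0.33, TopHat2 2.1.0 and the TAIR10 genome build. The HTSeq version, the annotation release, the strand setting and the counting mode were not given in the sources used here, so reads of overlapping and antisense genes may not have been told apart. Each file held 32678 genes and 5 summary lines. The summary lines stayed out of library sizes and tests. Reads that aligned more than once had been tallied on a line of their own and assigned to no gene, so repeated genes and near-identical family members are under-counted. Reads in no gene made up 25.8%, 18.6% and 18.6% of the uniquely aligned reads in NRO of Col-0, nrpd1-3 and nrpe1-11, and 31.0%, 29.1% and 28.6% in RNA. Gene-level counts hold no position within or beyond a gene, so read-through past gene ends was not measured.

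All 279 organelle genes had 0 counts in every library, and the 32399 nuclear genes were analysed. Names, biotypes and the order of neighbouring genes came from an NCBI table of assembly TAIR10.1, which matched 31912 of these identifiers, and its gene positions served only for distances between neighbouring genes. Genes without a symbol in that table keep their identifiers.

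Within each assay, genes with at least 20 counts in 1 or more libraries were kept. Library sizes were scaled by trimmed mean of M values (TMM) in edgeR 4.0.16 (R 4.3.3, limma 3.58.1), and log2 CPM, counts scaled to a common library size, were taken with a prior count of 2. With 1 library per group these comparisons have no replicate check. A size rule took the place of a test: a log2 ratio of at least 1 in size, together with a 95% exact (Clopper-Pearson) conditional binomial interval of the ratio that excludes 1. That interval covers counting error only, and so do the floors below, since PCR reads without molecular identifiers are not independent molecules. Against a count of 0, ratios are bounds computed with a floor of 3 counts per library. These 3 counts equal 1.50, 0.342 and 0.323 CPM in NRO of Col-0, nrpd1-3 and nrpe1-11, and 6.26, 7.10 and 6.46 CPM in RNA. Targets and SDC are given as CPM with exact 95% Poisson intervals.

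A model with additive terms for assay and genotype was fitted to all 6 libraries with edgeR's quasi-likelihood test on genes with at least 20 counts in 2 or more libraries. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values in the text are edgeR's from this model. The model has 2 residual degrees of freedom. Its spread is the variation between assays in the response to genotype, not the spread between plants, and because the prior degrees of freedom were infinite it was shared by all genes. The common biological coefficient of variation was 0.183.

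Gene lists fixed in advance held 216 genes in 13 lists: Pol IV, Pol V and RNA-directed DNA methylation, other DNA methylation and heterochromatin factors, loci known as silenced by DNA methylation, Pol II and 3′ end formation, photosynthesis, the circadian clock, heat shock, early response to wounding, touch, cold and jasmonate, salicylic acid and defence, flowering, markers of other leaf cell types, dividing cells and root, and ribosomal RNA. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. That percentile describes these libraries and is not a p-value. Annotation classes were treated in the same way. For shared controls, 100 sets of unchanged groups were simulated.

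Genes named in the text follow a rule. The target genes come first. For each mutant come the 10 highest and 10 lowest genes by the smaller of both assays' log2 ratios, among genes that met the size rule the same way in both assays with at least 50 counts. Then come the 5 highest and 5 lowest of each comparison, the 8 highest and 8 lowest between assays, and up to 4 members of each list. Any other gene is marked as chosen after its values were seen. Groups, lists, tests, the naming rule and most alternatives were fixed before the data were examined.

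Alternatives were DESeq2 1.42.0 (Wald test and size factors), scaling by library totals, other filters, prior counts of 0.5 and 10, counts thinned to equal totals, a 4-fold rule, a model without the block, and leaving out each library in turn. A limma fit (ordinary t-test on log2 CPM) using the spread of each gene on its own, scaling without ribosomal RNA and the 5 most abundant genes, and neighbours without regard to strand were added after the data were seen. The table of names gives no strand, so the test of neighbours on the same strand could not be made as designed. Keeping organelle genes changed nothing, as they had no counts.

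The steps were tested on simulated data drawn from the real means and library sizes. The additive model recovered 13% of 100 genes changed 2-fold and 67% of 100 changed 4-fold for nrpd1-3, and 12% and 73% for nrpe1-11. For NRO against RNA it recovered 17% and 61%. False calls numbered 0 of 14009, 4 of 14013 and 2 of 13988 unchanged genes. The simulated spread was the model's own fitted trend, with no spread particular to a gene and no plant or library effect added. These false calls therefore do not measure the error rate in the real libraries. In NRO the size rule recovered 44% and 43% of 2-fold changes and 97% of 4-fold changes for either mutant. On simulated unchanged genes it called 173 and 154 of about 15586 and 15564 with counting error alone, and 700 and 682 when the spread of the additive model was added. In RNA it called 29 and 24 unchanged genes, and 146 and 133 with that spread.

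Gene counts differed between libraries. NRO gene counts totalled 2687149, 8185846 and 7504294 for Col-0, nrpd1-3 and nrpe1-11, and RNA gene counts 709905, 386011 and 493080. Alignments set aside as not unique numbered 14406062, 9496796 and 8511333 in NRO and 13094136, 5226359 and 6428879 in RNA. Fewer gene counts therefore do not show that a library was sequenced less, and the shares of ribosomal RNA that follow are of gene counts only. Ribosomal RNA genes took 30.3% (95% interval 30.2 to 30.3) of the Col-0 NRO counts, against 6.68% (6.66 to 6.70) and 6.66% (6.64 to 6.68) in the mutants. In RNA they took 54.0% (53.9 to 54.1), 38.4% (38.3 to 38.6) and 44.1% (44.0 to 44.3). Genes with at least 20 counts numbered 8501, 15218 and 15350 in NRO and 2529, 2272 and 2571 in RNA.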

Results

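Nascent RNA and steady-state nuclear RNA were counted per gene in leaves of Col-0 and of lines labelled nrpd1-3 and nrpe1-11, with 1 library per assay and genotype. Pol IV and Pol V are plant-specific relatives of Pol II that make the noncoding RNAs of RNA-directed DNA methylation, and the series asks how their loss affects Pol II transcription. NRO libraries held between 2687149 and 8185846 gene counts, the Col-0 library holding the fewest. RNA libraries held between 386011 and 709905 gene counts. No genotype had a replicate within an assay, so the intervals of log2 ratios between libraries cover counting error only.

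The target genes were examined first. NRPD1 (AT1G63020), the largest subunit of Pol IV, stood at 4.50 CPM in NRO of Col-0 (95% counting interval 2.06 to 8.53, 9 counts). In the NRO library labelled nrpd1-3 it stood at 10.7 CPM (8.66 to 13.1, 94 counts), 2.38 times the Col-0 level and higher by the 2-fold size rule. The NRO library labelled nrpe1-11 held 2.05 CPM (1.23 to 3.20, 19 counts), which did not meet the rule against Col-0 (log2 ratio −1.03). RNA counts of NRPD1 were 0, 8 and 3 in Col-0, nrpd1-3 and nrpe1-11. NRPE1 (AT2G40030), the largest subunit of Pol V, stood at 11.99, 9.23 and 8.83 CPM in NRO of Col-0, nrpd1-3 and nrpe1-11, from 24, 81 and 82 counts. Its RNA counts were 6, 6 and 8. Neither gene was lower in the line labelled as its mutant beyond counting error. Counts summed over a gene do not show an insertion within it, so they neither bear out nor exclude the allele labels, and since NRPD1 was higher in the library labelled nrpd1-3, each direction given for nrpd1-3 is that of the library with this label.

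SDC (AT2G17690), an F-box gene kept silent by DNA methylation, had 0 NRO counts in Col-0, and its level is taken as at most the floor of 3 counts per library. The NRO library labelled nrpd1-3 held 7.86 CPM (6.12 to 9.95, 69 counts), at least 5.25-fold that floor. The library labelled nrpe1-11 held 8.40 CPM (6.64 to 10.5, 78 counts), at least 5.61-fold that floor. In the additive model SDC rose in both lines (edgeR adjusted p = 0.000548 and 0.000252), but it was not called by DESeq2 or without the Col-0 NRO library (fitted log2 fold changes of 6.77 and 6.75, which are no bounds).

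**Figure D1:**
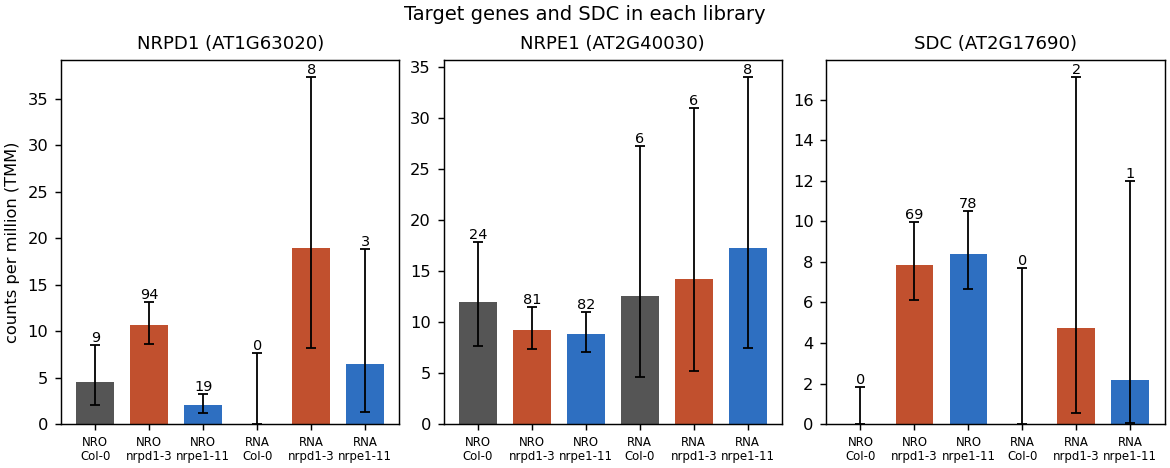
Bars give TMM-scaled CPM of NRPD1, NRPE1 and SDC in the 6 libraries, lines the exact 95% Poisson intervals, and the number over each bar its raw count. SDC had 0 NRO counts in Col-0 against 69 and 78 in the libraries labelled nrpd1-3 and nrpe1-11.

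The comparison of nrpd1-3 with Col-0 asks which genes differ when Pol IV is impaired. WES1 (AT4G27260), a GH3 enzyme that joins auxin to amino acids, rose in the line labelled nrpd1-3 with a fitted log2 fold change of 3.08 ± 0.384 (adjusted p = 8.86e-13). Here and below, ± gives an SE computed from the fitted fold change and the additive model's test statistic. It rests on the spread shared by all genes and is no precision of replicates. BGAL4 (AT5G56870), a β-galactosidase, rose by 2.08 ± 0.335 (adjusted p = 9.1e-08), and AT5G27850 by 3.59 ± 0.418 (adjusted p = 1.03e-14). AOC1 (AT3G25760), an allene oxide cyclase of jasmonate synthesis, fell by 2.74 ± 0.338 (adjusted p = 4.78e-13) and the jasmonate repressor JAZ8 (AT1G30135) fell by 2.39 ± 0.3 (adjusted p = 1.33e-12). DML1 (AT2G36490), also known as ROS1, a glycosylase that removes methylcytosine from DNA, fell by 2.87 ± 0.413 (adjusted p = 1.09e-09).

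Lowest by the smaller of both assays' log2 ratios, under the naming rule, was sks9 (AT4G38420), a relative of the multicopper oxidases, which fell by 3.88 ± 0.327 (adjusted p = 2.88e-28). RGP2 (AT5G15650), a UDP-arabinose mutase, fell by 2.52 ± 0.339 and the lipid acyl hydrolase PLA2A (AT2G26560) by 2.48 ± 0.318. TAT3 (AT2G24850), a jasmonate-responsive aminotransferase, fell by 2.30 ± 0.315, and IAR3 (AT1G51760), which cleaves amino-acid conjugates of hormones, fell by 2.15 ± 0.32. Adjusted p-values of these 4 genes lay between 4.43e-12 and 5.19e-09. All genes named so far in this comparison kept their call under DESeq2 and without any 1 library. Among genes higher in both assays, the log2 ratios of GSTF8 (AT2G47730), a glutathione transferase, were 1.64 in NRO and 1.63 in RNA, those of AT1G72910 2.04 and 2.17, and those of AILP1 (AT5G19140) 1.33 and 1.48. XYL1 (AT1G68560), an α-xylosidase of cell-wall xyloglucan, had log2 ratios of 2.29 and 1.64, and its call in the additive model was lost without the Col-0 NRO library (1.19).

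Loci with no Col-0 count stood at the top of the NRO comparison. AT5G27925 had 0, 313 and 8 NRO counts in Col-0, nrpd1-3 and nrpe1-11, at least 23.8-fold higher in nrpd1-3 than in Col-0. AT3G44215 had 0, 213 and 0 counts in NRO and 0, 42 and 0 in RNA, at least 16.2-fold and 15.9-fold higher in nrpd1-3. Both are annotated as pseudogenes, the class that holds transposon genes in this annotation. AT1G33840, AT5G35205 and AT5G35935 were at least 13.8-fold, 13.8-fold and 12.4-fold higher in nrpd1-3. At the other end, BAM5 (AT4G15210), a β-amylase, had 63 NRO counts in Col-0 and 9 in nrpd1-3, a log2 ratio of −4.58, and DFL2 (AT4G03400), a GH3 enzyme, had a log2 ratio of −3.64. The noncoding gene AT3G55485 was lower in NRO (log2 ratio −3.66) and near 0 in RNA (−0.01).

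By the size rule 1498 genes were higher and 1124 lower in NRO, of 16083, and 239 higher and 392 lower in RNA, of 3297. Scaling by library totals shifted the median of all genes by 0.51 (NRO) and 0.74 (RNA) on the log2 scale and gave splits of 3859 to 365 and 1104 to 99. Both assays called 87 genes higher, where independent lists would share 15.4, and 155 lower, against 33.2. Opposite calls numbered 5, against 45.4. Across the 3297 genes, which are not independent replicates, the log2 ratios of both assays correlated with r = 0.625 and rho = 0.556. The additive model called 565 genes higher and 776 lower of 14530. That total of 1341 became 277 under DESeq2, 0 when limma used each gene's own spread alone (1185 at an unadjusted p under 0.05, against 3077 in the edgeR model) and 0 in edgeR without the assay block (617 unadjusted). It was 556 without the Col-0 NRO library, 65 and 862 without the NRO libraries of nrpd1-3 and nrpe1-11, and 2231 and 565 without the RNA libraries of Col-0 and nrpd1-3.

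The comparison of nrpe1-11 with Col-0 asks the same for Pol V. AT5G27850 rose with a log2 fold change of 5.08 ± 0.416 (adjusted p = 8.71e-31), from NRO counts of 23 in Col-0 and 4652 in nrpe1-11. WES1 rose by 3.36 ± 0.384 (adjusted p = 7.39e-16). XYL1 rose by 3.06 ± 0.345 (adjusted p = 2.61e-16), BGAL4 by 2.75 ± 0.329 (adjusted p = 1.77e-14) and BXL1 (AT5G49360), a β-xylosidase, by 2.25 ± 0.382 (adjusted p = 1.7e-07). HBI1 (AT2G18300), a growth-promoting bHLH factor, rose by 2.52 ± 0.32 and KELP (AT4G10920), a transcriptional coactivator, by 3.02 ± 0.353, with adjusted p-values of 6.69e-13 and 3.5e-15.

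CYP94C1 (AT2G27690), which oxidises jasmonoyl-isoleucine, fell by 4.08 ± 0.378 (adjusted p = 4.25e-24), with RNA counts of 58 in Col-0 and 0 in nrpe1-11, a ratio of at most 0.0534. JAZ8 fell by 3.10 ± 0.313, JAZ10 (AT5G13220) by 2.63 ± 0.313 and JAZ7 (AT2G34600) by 2.42 ± 0.34, with adjusted p-values between 3.66e-20 and 1.03e-10. The allene oxide cyclase AOC2 (AT3G25770) fell by 2.15 ± 0.323 and IAR3 by 2.94 ± 0.341. WRKY18 (AT4G31800), a transcription factor of defence, fell by 2.99 ± 0.39 (adjusted p = 2.42e-12). The poly(A) polymerase PAPS1 (AT1G17980) fell by 2.68 ± 0.337 (adjusted p = 3.18e-13), DML1 by 2.14 ± 0.384 (adjusted p = 8.57e-07) and SRO5 (AT5G62520) by 3.52 ± 0.391 (adjusted p = 1.13e-16). sks9 fell by 5.49 ± 0.367 (adjusted p = 2.33e-46), with RNA counts of 55 and 0, a ratio of at most 0.0563. All genes named in this comparison so far kept their call under DESeq2 and without any 1 library.

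In NRO the highest ratios against 0 Col-0 counts were at AT1G33840, at least 22.2-fold with 309 counts, AT5G35205, at least 18.9-fold, AT5G35935, at least 9.85-fold, and AT4G25090, at least 7.76-fold. Lowest were AT4G14368 (log2 ratio −5.48), BAM5 (−5.25), AT5G41755 (−5.22) and the nitrate transporter gene NRT1.8 (AT4G21680, −4.45). In RNA, AT1G04555 had 0 counts in Col-0 and 50 in nrpe1-11, at least 17.2-fold higher, while its NRO log2 ratio was 0.94. ARGAH1 (AT4G08900), an arginase, had 2 and 66 RNA counts in Col-0 and nrpe1-11 and an NRO log2 ratio of 0.21.

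By the size rule 1948 genes were higher and 1778 lower in NRO, and 463 higher and 628 lower in RNA. Library totals shifted the median by 0.71 and 0.52 and gave splits of 5676 to 515 and 972 to 330. Both assays called 203 genes higher, against 45.5 for independent lists, and 371 lower, against 108. Opposite calls numbered 3, against 141, and the log2 ratios correlated across genes with r = 0.737 and rho = 0.709. The additive model called 1009 genes higher and 1677 lower. The total of 2686 became 932 under DESeq2, 0 when limma used each gene's own spread alone (1749 at an unadjusted p under 0.05, against 4217) and 0 in edgeR without the assay block (1220 unadjusted). It was 1337 without the Col-0 NRO library, and 1679 and 410 without the NRO libraries of nrpd1-3 and nrpe1-11.

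**Figure D2:**
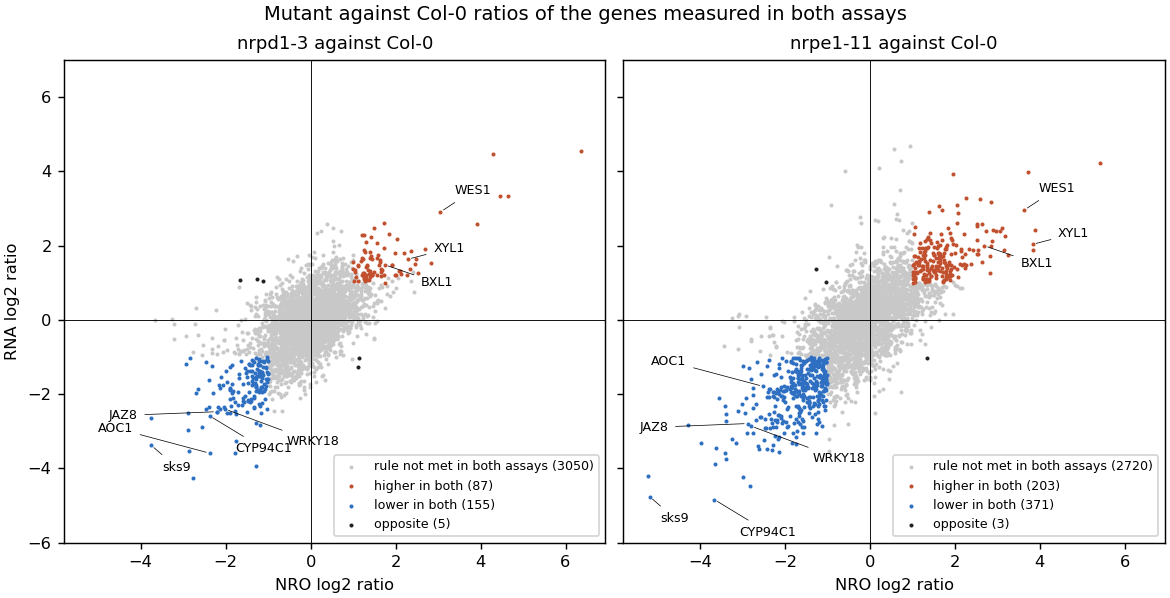
Each point is a gene counted in both assays (3297), placed by its log2 ratio to Col-0 in NRO (x axis) and in RNA (y axis), with nrpd1-3 and nrpe1-11 in separate panels and colours for genes that met the 2-fold size rule in both assays. Points called the same way in both assays (87 higher and 155 lower for nrpd1-3, 203 and 371 for nrpe1-11) outnumber those called in opposite ways (5 and 3).

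Direct comparison of the mutants asks where loss of Pol V differs from loss of Pol IV. NRPD1 itself was lower in NRO of nrpe1-11 than of nrpd1-3, with a log2 ratio of −2.23 (ratio 0.191, counting interval 0.110 to 0.315). Of 177 measured pseudogenes, 51 were lower in nrpe1-11 than in nrpd1-3 and 4 higher, with a class median of −0.29. After thinning to equal totals 17 were lower and 1 higher of 88, with a median of −0.16. AT5G27925 (313 counts in nrpd1-3 and 8 in nrpe1-11) and AT3G44215 (213 and 0) are members of this class. Of 25 photosynthesis genes 1 was higher and 0 lower in NRO of nrpe1-11, and 3 and 0 in RNA, with median log2 ratios of 0.37 and 0.71, both above all random lists. By the size rule 538 genes were higher and 749 lower in NRO of nrpe1-11, and 159 and 175 in RNA. Under library totals these splits became 965 to 471 and 91 to 317, with median shifts of 0.20 and −0.22. These differences between single libraries have no replicate check.

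Agreement between the mutants was examined because both are compared with the same Col-0 library. In NRO 1008 genes were higher and 786 lower in both mutants, against 181 and 124 for independent lists and 142 and 62.9 in simulated unchanged groups that share the control. In RNA 186 were higher and 333 lower in both, against 33.6 and 74.7 for independent lists and 19.9 and 9.66 in the simulation. AT4G20365 and AT5G42645 were the only genes called in opposite ways, both in NRO. Of the genes counted in both assays, 71 were higher and 138 lower in all 4 comparisons, WES1, BGAL4, sks9, RGP2 and JAZ8 among them. Log2 ratios of the mutants correlated with r = 0.865 in NRO (0.545 in simulated unchanged groups) and 0.806 in RNA (0.488). Covariances were 0.656 against 0.0894 simulated in NRO, and 0.743 against 0.129 in RNA. With the controls kept apart, nrpd1-3 in NRO correlated with nrpe1-11 in RNA at r = 0.480 and nrpd1-3 in RNA with nrpe1-11 in NRO at r = 0.746, where simulation gave values near 0 (−0.000483 and −0.000386). Part of the excess within an assay may come from the shared control, and genes are not independent replicates. Agreement across assays can still come from a difference of the Col-0 plants present in both assays, which the simulation does not model.

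NRO was compared with RNA, with genotype as a block, to ask which transcripts are relatively more abundant among nascent than among steady-state nuclear RNA. Early-response genes stood higher in NRO. Of the 22 wounding, touch, cold and jasmonate genes 21 were higher and 0 lower, with a median log2 fold change of 2.07. Over all 14530 genes 2429 were higher and 1436 lower. The rise was not particular to this list, as 10 of 14 salicylic acid and defence genes were higher and 0 lower. Photosynthesis genes went the other way, with 1 higher and 7 lower of 25, and clock genes with 1 and 6 of 15. CYP94C1 was higher in NRO by 2.53 ± 0.325 (adjusted p = 6.51e-13) and JAZ7 by 1.68 ± 0.282 (adjusted p = 7.18e-08). The U1 spliceosomal RNA gene U1.5 (AT1G08115) was lower, at −4.40 ± 0.43 (adjusted p = 1.24e-21). The genes at the top of this comparison had no RNA count at all, such as CML42 (AT4G20780), a calmodulin-like gene with 29, 108 and 64 NRO counts, and SAUR23 (AT5G18060), an auxin-responsive gene with 4, 118 and 186.

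The model called 2429 genes higher and 1436 lower in NRO of 14530. With counts thinned to equal totals only 2899 genes passed the filter, and it called 855 higher and 868 lower. The excess of higher genes did not hold in that smaller set, which is not the same set of genes. DESeq2 called 1238 and 691. The total of 3865 became 1056 without the genotype block and 0 when limma used each gene's own spread alone (2922 at an unadjusted p under 0.05, against 5298). It was 1780 and 1919 without the NRO libraries of nrpd1-3 and nrpe1-11, and 1745 and 2007 without their RNA libraries. ARGAH1, AT1G04555 and AT5G22320 changed direction in this comparison when a nrpe1-11 library was left out (0.69, 6.82 and 1.17 without the RNA library), so no direction is given for them.

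Among the fixed gene lists, that of Pol IV, Pol V and RNA-directed DNA methylation factors had NRO medians inside the range of random lists in both mutants. In NRO 17 of 26 members were measured, 3 higher and 1 lower in nrpd1-3 and 3 higher and 2 lower in nrpe1-11. Over all genes measured in NRO, 16.3% and 23.2% met the rule in nrpd1-3 and nrpe1-11. RDR2 (AT4G11130), the RNA polymerase that copies Pol IV transcripts, had 0, 27 and 25 NRO counts in Col-0, nrpd1-3 and nrpe1-11, at least 2.05-fold and 1.80-fold higher, and IDN2 (AT3G48670) had log2 ratios of −1.59 and −1.23. The additive model called 0 and 1 of 15 members (0 and 0 adjusted over the list alone), the 1 being CRT1 (AT4G36290), also known as MORC1, chosen after its values were seen. Of the other DNA methylation factors, 11 of 15 were measured in NRO, 2 higher and 1 lower in nrpd1-3 and 1 and 1 in nrpe1-11. The model called 1 higher and 1 lower in nrpd1-3 and 2 lower in nrpe1-11, the same numbers adjusted over the list alone. DML1 fell in both mutants. SUVH4 (AT5G13960), a histone methyltransferase, was called in nrpd1-3 at 1.71 ± 0.477 (adjusted p = 0.00708), but not by DESeq2 (1.38) and not without the Col-0 NRO library (−0.02). Of the 8 loci known as silenced only SDC reached the filter, which a locus silent in Col-0 can reach only through the mutant libraries. The model called it in both mutants, though not under DESeq2 or without the Col-0 NRO library. It was called over the list alone as well, an adjustment over 1 tested gene.

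Pol II and 3′ end formation genes were nearly all within the rule. Of 20 measured in NRO, 0 differed in nrpd1-3 and 2 were lower in nrpe1-11, PAPS1 (log2 ratio −2.32) and CSTF77 (AT1G17760, −1.10), a subunit of the cleavage stimulation factor. In RNA 1 of 10 was lower in each mutant, PAPS1 with log2 ratios of −1.81 and −2.67. The model called 1 lower of 20 in each mutant (1 adjusted over the list alone), and PAPS1 in nrpd1-3 (−1.30 ± 0.315) lost its call without either NRO mutant library (−1.73 and −1.18) or without the RNA library of nrpd1-3 (−0.93).

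Photosynthesis genes were lower in NRO of nrpd1-3 in 7 of 25 cases and higher in 0, with a median of −0.45 at percentile 0.25 of matched random lists. RNA of nrpd1-3 showed 1 higher and 0 lower (median −0.26, percentile 29.7). In nrpe1-11 2 were higher and 2 lower in NRO (median −0.03), and 4 higher and 0 lower in RNA (median 0.37, percentile 99.8). The model called 5 lower in nrpd1-3 (6 adjusted over the list alone), and 3 higher and 1 lower in nrpe1-11 (3 and 1 adjusted over the list alone). PORB (AT4G27440), which makes chlorophyllide, rose in nrpe1-11 by 1.97 ± 0.3 (adjusted p = 4.16e-09). RBCS3B (AT5G38410), a small subunit of Rubisco with near-identical copies and hence uncertain counts, fell in nrpd1-3 by 1.77 ± 0.308 (adjusted p = 1.11e-06), and was not called without the NRO library of nrpd1-3 (−1.20).

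Clock genes showed 2 higher and 2 lower of 16 in NRO of nrpd1-3 and 5 and 1 in nrpe1-11. In RNA 1 was higher and 1 lower of 7 in each mutant. The model called 2 higher in nrpd1-3 and 2 higher and 1 lower in nrpe1-11 of 15, the same adjusted over the list alone. RVE1 (AT5G17300), which links the clock to auxin, rose in nrpe1-11 by 2.46 ± 0.483 (adjusted p = 9.88e-06). Heat-shock genes were measured for 8 of 16 members in NRO, 1 higher in nrpd1-3 (median 0.93, percentile 97.2) and 2 higher and 1 lower in nrpe1-11. HSP90.1 (AT5G52640) had log2 ratios of 1.44 and 1.39. The edgeR model called 0 of 5 in either mutant, at an adjusted p under 0.05 and adjusted over the list alone.

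Wounding, touch, cold and jasmonate genes moved in both directions. In NRO 5 of 22 were higher and 2 lower in nrpd1-3, and 5 and 5 in nrpe1-11. RNA of 21 members showed 2 higher and 5 lower in nrpd1-3 and 1 and 7 in nrpe1-11. The model called 5 higher and 4 lower in nrpd1-3 (5 and 5 adjusted over the list alone) and 4 and 5 in nrpe1-11 (5 and 7). Of the 8 jasmonate members of this list, 2 met the rule lower in NRO of nrpd1-3 and 5 in each of the other 3 comparisons with Col-0. While JAZ8 and JAZ10 were lower in all 4, DREB1A (AT4G25480), a cold-response factor, had NRO log2 ratios of 2.29 and 2.12. ERF5 (AT5G47230) and CBF1 (AT4G25490), an ethylene-response and a cold-response factor chosen after their values were seen, had NRO log2 ratios of 2.33 and 2.45 in nrpd1-3 and 2.08 and 1.96 in nrpe1-11.

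**Figure D3:**
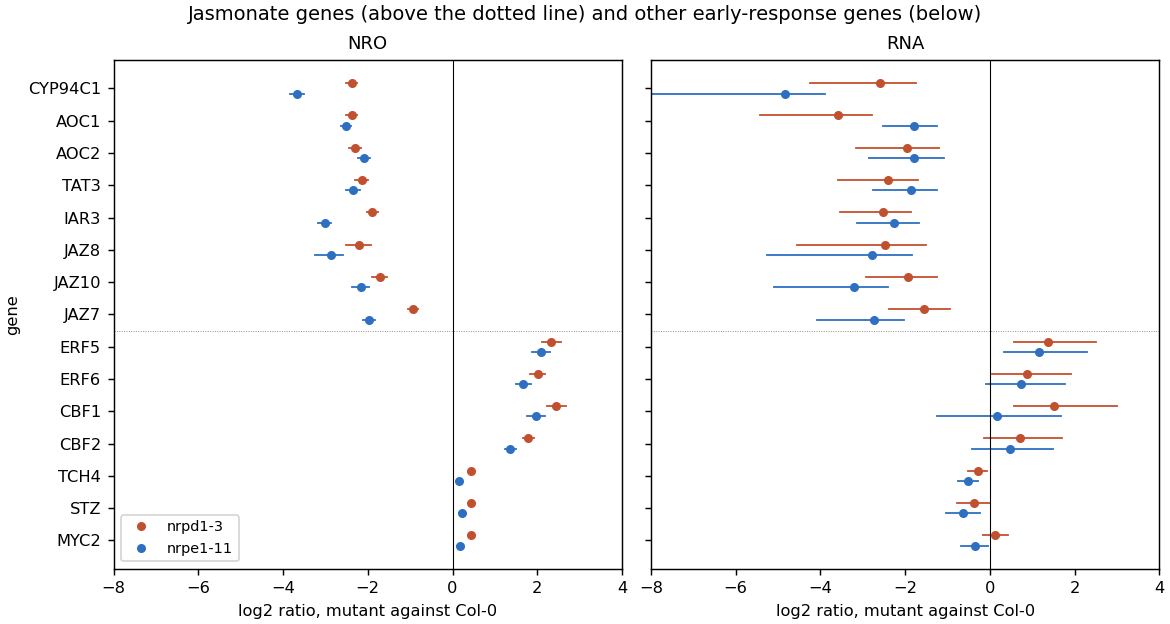
Points give the log2 ratio to Col-0 of 8 jasmonate genes (above the dotted line) and 7 members of the wounding, touch, cold and jasmonate list (below it) in NRO and RNA for each mutant. Lines give the 95% counting interval, drawn to the edge of the axis where they run past it. Both sets were chosen after their values were seen. The lower set holds MYC2, a jasmonate member of that list, and the jasmonate members JAZ1, JAZ5, LOX3 and AOS are not drawn. CYP94C1 lies at −2.38 and −3.66 in NRO, ERF5 at 2.33 and 2.08.

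Salicylic acid and defence genes showed 1 lower of 14 in NRO of nrpd1-3 and 2 higher in nrpe1-11, and in RNA 1 higher of 8 and 2 higher and 1 lower. The model called 1 higher and 2 lower in nrpd1-3 (the same adjusted over the list alone) and 2 higher and 1 lower in nrpe1-11 (2 and 2). WRKY70 (AT3G56400), a regulator of salicylic acid signalling, rose in nrpe1-11 by 1.62 ± 0.332 (adjusted p = 2.44e-05). The flowering list had 1 of 11 members measured, AGL20 (AT2G45660), with NRO log2 ratios of −0.17 and 0.67 and 0 calls in either mutant, also adjusted over the list alone. Markers of other leaf cell types showed 2 higher and 0 lower of 11 in NRO of nrpd1-3 and 4 and 3 in nrpe1-11, with medians of 0.20 and 0.20 inside the range of random lists. After thinning 7 members had medians of 0.82 (percentile 99.05) and 1.25 (99.86), and with at least 100 counts 6 had 0.49 (94.24) and 0.74 (97.63). In RNA 0 of 4 differed in nrpd1-3 and 2 were higher in nrpe1-11. The model called 1 higher of 10 in nrpd1-3 (1 adjusted over the list alone) and 4 higher and 1 lower in nrpe1-11 (4 and 2). KCS6 (AT1G68530), an enzyme of epidermal wax synthesis, had NRO log2 ratios of 1.46 and 1.27.

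Genes of dividing cells and root were higher in NRO of nrpd1-3 in 3 of 5 cases (median 1.03, percentile 98.8) and in 0 of 5 in nrpe1-11. Without the count filter the 8 members counted had a median of 0.21 in nrpd1-3, at percentile 60.1. The model called 2 higher in nrpd1-3 (3 adjusted over the list alone) and 1 in nrpe1-11 (2). PYK10 (AT3G09260), a β-glucosidase of roots, was higher in RNA of both mutants (log2 ratios 1.67 and 2.43), and SCR (AT3G54220), a root patterning factor, had NRO log2 ratios of 1.03 and 0.72. Of the 4 ribosomal RNA genes 2 were lower in NRO of nrpd1-3 and 3 in nrpe1-11 (medians −1.06 and −2.04, percentiles 0.47 and 0.08), and 2 and 1 in RNA. The model called 1 and 2 lower, the same adjusted over the list alone. Copies of these genes are near-identical, so their counts are uncertain.

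Annotation classes were compared last. Small nucleolar RNA genes were lower in NRO in 22 of 27 cases in nrpd1-3 and 21 of 27 in nrpe1-11, with medians of −1.64 and −1.996, below all 10000 random lists. In RNA 7 were measured, with medians of −0.47 and 0.10. Small nuclear RNA genes were lower in NRO in 7 of 11 cases in each mutant (medians −1.31 and −1.27). MicroRNA genes went the other way, 11 of 30 being higher in nrpd1-3 and 15 in nrpe1-11, none lower, with medians of 0.96 and 1.22 above all random lists. Without the count filter 12 microRNA genes were higher and 1 lower in nrpd1-3, and 15 and 2 in nrpe1-11. Pseudogenes were higher in 55 and lower in 12 of 177 cases in nrpd1-3 (median 0.46, percentile 99.99), and after thinning in 27 and 10 of 88, the median of 0.19 (percentile 94.58) lying inside the range of random lists. In nrpe1-11 the numbers were 28 and 25 (median 0.05), and without the count filter 29 and 43. Long noncoding RNA genes were lower in 24 and higher in 10 of 126 cases in nrpe1-11 (median −0.23, percentile 0.05), and lower in 14 and higher in 6 in nrpd1-3 (median −0.07, percentile 6.05). Transfer RNA genes were higher in 4 of 13 cases in nrpd1-3 (median 1.37, percentile 98.8) and in 2 of 13 in nrpe1-11 (median 0.73, percentile 76.1).

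**Figure D4:**
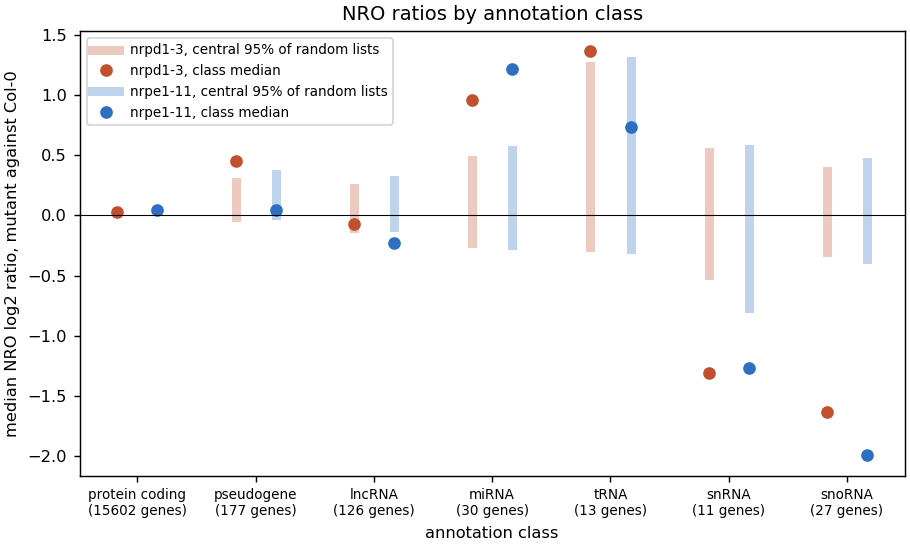
Points give the median NRO log2 ratio to Col-0 of each annotation class, with the number of genes, and bars the central 95% of medians of matched random lists, for nrpd1-3 and nrpe1-11. Medians of small nucleolar RNA genes (−1.64 and −1.996) lie below the bars and those of microRNA genes (0.96 and 1.22) above them.

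Genes beside a strongly transcribed neighbour were examined because read-through from a neighbour would add counts to them. Of genes within 500 bp of a neighbour in the upper 25% of Col-0 NRO, 1933 were measured, with median log2 ratios of −0.00 in nrpd1-3 (percentile 24.8 of random lists) and −0.08 in nrpe1-11 (percentile 0). With the neighbour in the upper 10% the medians were −0.06 and −0.17. The 805 genes more than 2000 bp from both neighbours had medians of 0.27 and 0.29, above all random lists. In RNA 408 genes within 500 bp of a neighbour in the upper 25% had medians of −0.09 (percentile 5.49) and −0.17 (0.07), and 197 distant genes 0.20 (99.99) and 0.20 (96.62). Strand was not known, so neighbours on either side were counted alike. Neighbours were ranked by the same Col-0 NRO library that is the denominator of the NRO ratios. Signal of that library shared by adjacent genes would lower these ratios, so the medians cannot decide on read-through.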

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

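Tests of scaling and of loss of Pol IV or Pol V for the small nucleolar RNAs, all tests for the jasmonate genes, and the tests of Col-0 depth and of loci seen in both mutants for the silent loci were chosen only after the result was seen.

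Genes called in opposite ways by NRO and RNA in the same line stood out as differences between groups, and the difference was not tested. For nrpd1-3 the NRO log2 ratios were −1.26 at AT1G27520 (1.09 in RNA), −1.67 at FBP (1.06), −1.12 at ML3 (1.05), 1.106 at AT1G73530 (−1.26) and 1.13 at CYP72A8 (−1.02). For nrpe1-11 they were −1.03 at ABCG24 (1.04 in RNA), −1.27 at AT1G77680 (1.38) and 1.34 at AT1G78820 (−1.01). The pseudogenes AT4G20365 and AT5G42645 differed between the mutants in NRO, which was not tested either. AT4G20365 had 3, 181 and 0 counts in Col-0, nrpd1-3 and nrpe1-11 and AT5G42645 had 6, 104 and 0, with log2 ratios of nrpd1-3 to Col-0 of 3.54 (ratio interval 4.64 to 67.4) and 1.88. Reads overlapping more than 1 gene, a count outside the comparisons, were taken as a share of themselves plus the gene counts without ribosomal RNA. That share was 0.807% and 0.882% in NRO of nrpd1-3 and nrpe1-11, above the 0.638% of Col-0.

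Small nucleolar RNA genes were lower in NRO of both mutants, and loss of Pol IV or Pol V cannot be told from a property of the 1 Col-0 NRO library. Were unlabelled nuclear RNA carried over into the Col-0 capture, a share of 40.9% or 56.6%, fitted on 3235 protein-coding genes, would predict medians of −1.24 and −1.67 for the 7 members counted in both assays, where −2.69 and −2.90 were observed (carry-over medians are of log2 ratios with 0.5 CPM added and so differ from the class medians), and this set was run first. For all 27 members, added after that, it would predict −0.63 and −0.58 against −1.58 and −1.91, but 20 of them did not pass the count filter in RNA, so carry-over may account for part of the drop and is left open. For small nuclear RNA genes it would predict −1.47 and −1.70 against −1.31 and −1.28 for the 8 counted in both assays, and −0.78 and −0.93 against −1.31 and −1.27 for all 11. The fitted share also takes up genotype differences present in both assays, so it does not measure carry-over alone and these predictions cannot decide. A relation with no shared library set the NRO ratio of 1 mutant against the NRO minus RNA level of the other. It gave r = 0.204 for the ratio of nrpd1-3 and −0.079 for that of nrpe1-11 over 3297 genes, which leaves carry-over open. Scaling as the whole cause is argued against by the medians under library totals, −1.13 (−1.84 to −0.96) and −1.28 (−1.53 to −0.45), though it moved the size of the drop, and the percentile of 0 under 4 scalings tests nothing, as a size factor shifts all genes alike.

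Of the 8 jasmonate members of the fixed list, 2 were lower in NRO of nrpd1-3 and 5 in each other comparison. Depth or scaling stays open: of 8 jasmonate genes picked because they were lower, 3 of them in that list, 6 or more met the rule in all 4 comparisons across size factors, library totals and thinning, and genes picked for the pattern cannot test it. More recent wounding or touch of the Col-0 plants is left open. In NRO the touch, cold and ethylene-response members had a median log2 ratio of 0.47 (0.16 to 1.67) in the mutant where it was lower. That goes against wounding only if these genes and the jasmonate genes stay raised equally long, which was not tested. In RNA their medians were −0.01 and −0.47 (−0.63 to 0.34). These intervals resample genes within single libraries. Harvest at another time of day is left open, as morning minus evening clock genes ranged from −0.76 to 1.87 with 1 evening gene measured in RNA. With 1 Col-0 library per assay, a difference of the Col-0 plants for a reason other than genotype could not be told from genotype.

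Loci with no Col-0 NRO count had counts in the mutants, SDC and BOA among them. Lower depth alone, with reads as independent draws, is argued against by 29 and 21 such genes where the levels of nrpd1-3 and nrpe1-11 predict at least 10 counts. Poisson sampling would give 0.022 and 0.020. PCR reads are not independent molecules, so a Col-0 library of few distinct molecules is left open. The 16 loci that reached this level in NRO of both mutants are by their selection not counts on a single library. Independent lists would share 0.159, but that number takes no account of expression shared by the mutants, so the excess tests nothing further. Counts common to both mutant libraries for another reason were not tested. Of loci at this level in 1 mutant, the 5 of nrpe1-11 held 16 to 43 NRO counts in nrpd1-3, which argues against counts on a single library. The 13 of nrpd1-3 held 20 to 42 in nrpe1-11, which argues likewise, except AT5G27925, AT3G44215, AT1G53810 and AT3G62725. These held 8, 0, 7 and 2, and 19, 42, 3 and 0 RNA counts in nrpd1-3. For AT5G27925 and AT3G44215, with 0 counts in Col-0 RNA, the RNA counts of nrpd1-3 argue against counts on a single library. AT1G53810 and AT3G62725 are left open. For the loci as a set the test by RNA leaves counts on a single library open. Of all measurable loci, 57.1% (95% interval 28.9 to 82.3) and 53.3% (26.6 to 78.7) were counted in RNA of the same mutant and not of Col-0. Among all genes with no Col-0 NRO count these shares were 8.21% and 12.5%. Reads shared between copies of a repeat are left open, because reads aligned more than once were assigned to no gene, yet 37.9% and 14.3% of the loci are annotated as pseudogenes, against 0.821% and 0.543% of genes at that level.

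After thinning to equal totals 17 pseudogenes were lower in nrpe1-11 than in nrpd1-3 and 1 higher, with a median log2 ratio of −0.16 (percentile 0.04). Against Col-0 thinning brought the class in nrpd1-3 back inside the range of random lists, from 0.46 (percentile 99.99) to 0.19 (94.58). Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real split, reached 3865 genes in edgeR, the highest other giving 0 (18 to 637 at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05. Genes within 500 bp of a strongly transcribed neighbour had medians of −0.001 and −0.081. Read-through is left open, as the neighbours were ranked by the Col-0 library used in the ratios.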

How the results depend on the processing

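Median-ratio size factors, a prior count of 0.5 and scaling without ribosomal RNA and the 5 most abundant genes moved no summary total by over 1.5 times. Within the totals, median-ratio factors gave 1841 higher and 1887 lower in NRO of nrpe1-11, against 1948 and 1778, and scaling without ribosomal RNA gave 1268 and 1453 in the additive model of nrpe1-11, against 1009 and 1677. Named genes had the same status, called or not, in 2862 pairwise cases, weakened in 147 and strengthened in 41, with 0 reversed. In the additive model the status stayed in 3093 cases, weakened in 729, strengthened in 50 and reversed in 16. Gene lists stayed inside, or stayed outside, the central range of random lists in 423 cases. In 10 they left it and in 5 they came back inside. Thinning moved out the leaf cell markers in NRO of both mutants, the clock list between the mutants in NRO, the defence list in RNA of nrpd1-3 and the wounding list between the mutants in RNA, and brought back the wounding list in NRO of nrpd1-3. At least 100 counts brought that list back too and moved out the leaf cell markers in NRO of nrpe1-11. No paired analysis was possible because each group had 1 library, so replicate numbers pair nothing beyond the blocks for assay and genotype in the additive model. Keeping organelle genes gave no values of its own, since they had no counts. Unless the setting's construction shows it (fewer genes, libraries or a stricter rule), the cause was not tested.

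Library totals gave 4224 and 6191 calls in NRO of nrpd1-3 and nrpe1-11, 1203 in RNA of nrpd1-3, and 484 in both assays of nrpd1-3. Without a filter the comparison of the mutants gave 1956 calls in NRO and 620 in RNA, RNA against Col-0 gave 1094 and 1736, and both assays of nrpd1-3 gave 377. With at least 100 counts NRO gave 1305, 2113 and 396 calls, RNA 111, 221 and 58, and both assays 55 and 135. A prior count of 10 gave 657 calls between the mutants in NRO and 352, 719 and 140 in RNA. Thinning gave 846 between the mutants in NRO. The 4-fold rule gave 603, 942 and 126 calls in NRO, 83, 250 and 31 in RNA, and 24 and 98 in both assays.

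In the additive model DESeq2 called 277, 932 and 1929 genes for nrpd1-3, nrpe1-11 and NRO against RNA (1259, 2133 and 3528 at an unadjusted p under 0.05). Thinning gave 462, 916 and 1723 calls, of 2899 genes tested instead of 14530. Using each gene's own spread, limma called 0 in each (1185, 1749 and 2922 unadjusted). Without the block edgeR called 0, 0 and 1056 (617, 1220 and 3693 unadjusted). Leaving out 1 library gave 65 to 2231, 410 to 3275 and 1745 to 3982 calls.

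Correlations of the mutants with at least 100 counts were 0.872 within RNA, 0.416 for nrpd1-3 in NRO with nrpe1-11 in RNA, and 0.848 for the reverse pair, and Spearman values of these last pairs were 0.431 and 0.7. Without a filter, pseudogenes numbered 72 calls in NRO of nrpe1-11 with the balance reversed (29 higher and 43 lower), and 117 against nrpd1-3 (6 and 111).

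For NRO against RNA, AT1G04555 stood at 1.18 in DESeq2 and 0.53 with its own spread. Leaving out 1 library at a time, it ranged from −3.75 (without the NRO library of nrpd1-3) through 5.96 (without the NRO library of nrpe1-11) to 6.82 (without the RNA library of nrpe1-11). AT5G22320 ranged from −3.73 to 1.17 over these libraries, with 1.05 without the NRO library of nrpe1-11, and ARGAH1 from −4.54 to 0.69, with 0.57 there. In nrpe1-11 ARGAH1 ranged from −0.026 (without the RNA library of nrpe1-11) to 5.95. In nrpd1-3 AT3G18170 ranged from −1.46 to 0.19, SAUR23 from −0.30 to 2.71, SUVH4 from −0.019 to 2.48, BOA from −0.69 to 7.93 (fitted values, no bounds) and CYCD3;1 from −0.21 to 1.28. In nrpe1-11 AT1G26380 ranged from −1.61 to 0.13 and C2 from −0.12 to 2.098. In these last 7 genes the reversed end came without the Col-0 NRO library. Depth limits the RNA assay most, where 3 counts equal at least 6.26 CPM.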

Other observations

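Of 178 microRNA precursor genes 30 passed the count filter in NRO. Among these, 11 were higher by the size rule in nrpd1-3 and 15 in nrpe1-11, 0 lower in either. Without the filter 1 was lower in nrpd1-3 and 2 in nrpe1-11, against 12 and 15 higher. Those named here were chosen after their values were seen. MIR398c, whose product targets superoxide dismutase transcripts, had 186, 2828 and 3233 NRO counts in Col-0, nrpd1-3 and nrpe1-11, log2 ratios of 1.79 and 1.90. MIR159a, which restrains GAMYB-like factors, had log2 ratios of 1.78 and 2.05, MIR166a, which restrains HD-ZIP III factors of leaf polarity, 1.69 and 2.02, and MIR850 1.44 and 2.39. MIR163 went the other way at −0.99 and −0.50, which did not meet the size rule.

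The next 3 genes, known to respond to darkness, light or sugar, were also chosen after their values were seen, and no list of such genes was tested. DIN10, a raffinose synthase-like gene, had log2 ratios to Col-0 of 1.69 in NRO and 2.14 in RNA of nrpe1-11, against 0.50 and 1.43 in nrpd1-3. BBX14, a B-box factor, had 1.34 and 1.95 in nrpe1-11 against 0.18 and 1.02. The asparagine synthetase gene ASN1 met the rule in neither mutant, with NRO log2 ratios of 0.20 and 0.57.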
